A study of Mus musculus with 4 samples.

How the data were processed

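RNA from sorted splenic T cells of castrated and sham operated male mice was measured on 4 one-colour arrays, 2 per group. Per the labels' protocols, RNA was extracted with Trizol and labelled with biotin during in vitro transcription, and cells were collected 4 weeks after surgery. Each array was a pool of 3 mice, so that the spread between the 2 arrays of a group is a spread between pools and says little about single mice. The deposited values are intensity on a linear scale, 1 per probe set and array, already summarised and normalized by the authors. The background correction, the summary method and the normalization are not given in the sources used here. The deposited normalization was kept because the medians and interquartile ranges of the 4 arrays lay within 0.1 log2 of each other, a rule set before the data were examined. The log2 medians were 4.77, 4.77, 4.79 and 4.78 for sham 1, sham 2, castrated 1 and castrated 2, and the interquartile ranges were 3.64, 3.68, 3.72 and 3.69. For arrays, the small number of samples limits the precision of every value.

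Of 45140 probe sets, 104 control probe sets were set aside from the comparison and 1 probe set had no value on the sham arrays. Intensities under 16 were set to 16 and log2 values were taken, so that differences of probe sets near the floor are understated. Where both arrays of a group lay at the floor, the fold is given as a lower bound. Probe sets with a mean log2 value at or above the 50th percentile were tested, which left 22518. Gene names came from the platform annotation, with gene numbers looked up in a RefSeq table of the GRCm38.p6 assembly. There, 28898 probe sets had 1 gene, 551 had several and 15587 had none, and 28689 of the first kind were found by gene number. Probe sets without a name were tested and counted but are not named. No coordinates were used. A gene was represented by its brightest tested probe set, and the text says where another tested probe set differs in call or direction. Of 3845 genes with at least 2 tested probe sets, a dimmer one rose for 333 genes, of which 188 had a brightest probe set that did not pass. A dimmer one fell for 447 genes, of which 239 had a brightest probe set that did not pass. In each direction 4 genes had a brightest probe set called the opposite way. Some probe sets can cross-hybridise with related genes, as in the Klra family and the Hspa1a and Hspa1b pair, so single members of such families are uncertain.

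The difference castrated minus sham was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The prior degrees of freedom were 3.68. Errors given with a difference are the moderated standard errors of that fit. The median difference over the tested probe sets was 0.03 log2. Lists of genes were tested with camera with a preset correlation of 0.01, adjusted over the 31 of 34 lists that had at least 5 tested genes. Camera was also run with a correlation estimated from the data, and fry beside it. With the preset correlation, camera p-values rest mainly on the spread between genes and say little about the spread between the 2 pools of a group. With an estimated correlation, camera has only the few residual degrees of freedom that 4 arrays leave. A list can then hardly pass the adjustment over 31 lists, so a failure to pass there is weak evidence against a list. With the preset correlation 2 lists were higher and 4 were lower, with an estimated correlation none was called in either direction, and fry called the glycolysis list as higher and the CD8 T cell list as lower (adjusted p = 0.0374). The fry test asks whether the genes of a list move on balance in one direction, and it does not compare the list with other genes. The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, unless stated otherwise. The rule named, among genes past the threshold whose groups did not overlap, the 12 with the largest rises and the 12 with the largest falls, up to 4 genes with the smallest p from each list, and a fixed set of helper, gate and sex-linked genes. Some genes that the rule named, from the lists and from the fixed set, are not reported here. Genes known only by a clone or a number were counted but not named. The median, the mean and the camera direction of a list differed in sign for glucocorticoid, Th17, immediate early, NF-kappaB, cholesterol synthesis, neutrophil and dendritic cell genes, where members moved both ways. Adjusted over the list alone, the genes that rose and fell numbered 3 and 3 for glucocorticoid, 3 and 4 for immediate early, 3 and 3 for NF-kappaB, 12 and 2 for memory, 9 and 5 for survival, 1 and 3 for cholesterol, 3 and 3 for dendritic cell and 5 and 1 for heat shock genes. For each list not given here or with its values, these counts were those over all tested probe sets, except 0 for oxidative phosphorylation and erythroid genes.

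The steps were tested on simulated data made from the real intensities, with 200 of 22518 probe sets changed in each of 10 runs. The fit recovered 0.4% of the 2-fold changes and 46.9% of the 4-fold changes, with a mean of 0.5 false calls per run. Recovery after the adjustment depends on the share of probe sets that change. The real comparison gave 3638 calls, so these rates do not carry over to it. A list of genes shifted by 0.5 log2 was called in 10 of 10 runs, and 0 of 300 unchanged lists were called. The simulated genes varied independently of each other, so these runs cannot show false calls of lists whose genes are correlated.

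Alternatives covered quantile normalization and median centring, no filter and a filter at the 75th percentile, a floor of 32, log2 of the intensity plus 50, the replicate number as a block, trend and robust variance models, the mean of all probe sets of a gene, other set tests, other thresholds and each array left out in turn. One alternative was added after seeing the data. Figures were drawn with matplotlib 3.10.9.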

Results

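Gene expression in splenic CD4 T cells was compared between castrated and sham operated male mice, to ask how the loss of testicular androgens affects these cells. The mice carried green fluorescent protein (GFP) as a reporter of Foxp3, the transcription factor that defines regulatory T cells. Cells positive for CD3 and CD4 and negative for GFP, that is helper T cells without the regulatory subset, were sorted from the spleen 4 weeks after surgery. Each array held RNA pooled from 3 mice, and each group had 2 arrays, which covered 6 mice per group. The measurement was the intensity of each probe set, a group of short probes for 1 transcript, on a linear scale. The median intensity was 27.2 on each sham array, 27.6 on the first castrated array and 27.4 on the second. Between 37.0% and 37.4% of the probe sets of an array lay at or under the floor of 16. Across the 22518 tested probe sets, Pearson's r was 0.987 between the sham arrays, 0.978 between the castrated arrays and 0.931 to 0.945 between arrays of different groups. These correlations are across probe sets, which are not independent replicates. The first principal component held 76.1% of the variance and separated the groups, and the second held 15% and separated the castrated arrays from each other.

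Interferon-induced genes were higher after castration, and markers of CD8 T cells, B cells, natural killer (NK) cells and monocytes were lower, in camera with a preset correlation. With a correlation estimated from the data the adjusted p was 0.86 for each of these 6 lists. Before adjustment, p in that camera test ran from 0.0447 for the CD8 T cell list to 0.429 for the interferon-gamma list. With 2 arrays per group that test can hardly call any list, so 0.86 is weak evidence against them. Single cytokine genes, among them Il21, Ifng and Tnf, were also higher. Among the named genes that passed the test, Il21, a cytokine of follicular helper cells, rose by 3.44 ± 0.55 log2 (SE, 2 arrays per group; adjusted p = 0.0185). The castrated arrays lay apart for Il21, and its rise was 2.55 without castrated array 2 and 4.33 without castrated array 1. Ffar2, a receptor for short-chain fatty acids, rose by 3.37 ± 0.33 (adjusted p = 0.00672), and Scn2b, a sodium channel subunit, by 3.18 ± 0.15 (adjusted p = 0.00351). A second tested probe set of Scn2b differed by 0.34 and did not pass. Klra8, a receptor of NK cells that lay near the floor on both castrated arrays, fell by 4.27 ± 0.17 (adjusted p = 0.00322). Clec4d, a lectin receptor of myeloid cells, fell by 4.07 ± 0.26 (adjusted p = 0.00351).

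The other 9 named genes with the largest rises past the test were Hspa1b, an inducible 70 kDa heat shock protein, Ifit1bl1, Rnf43, Cyp4f16, Ctnnd2, Apol7c, Spint1, Apol7a and Tnfsf14, a ligand of the tumour necrosis factor family. They rose by between 2.23 log2 for Tnfsf14 and Apol7a and 2.61 for Hspa1b. The difference of Apol7c was 1.79 without castrated array 2 and 2.97 without castrated array 1. Among the other 10 named falls, Ramp3 fell by 3.79 log2, Spry2 fell by 3.77, the complement receptor C5ar1 fell by 3.61 and Fosl2, a member of the AP-1 family, fell by 3.55. The endotoxin co-receptor Cd14 fell by 3.53, Usp2 fell by 3.38, the killer cell protease Gzma fell by 3.30 and Vps37b fell by 3.20. Ssty2, from a multicopy family of the Y chromosome, was at the floor on both castrated arrays and was at least 12.5-fold lower. Acod1, an enzyme of activated macrophages, was also at the floor there and was at least 10.97-fold lower.

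In all, 1708 probe sets rose and 1930 fell at an adjusted p under 0.05 in limma, of which 593 and 991 changed at least 2-fold. Taking the brightest probe set of each of 9892 genes, 850 genes rose and 737 fell. At an unadjusted p under 0.05 the number of probe sets was 7938. The 2 groups did not overlap for 64.8% of the tested probe sets, against 33.3% by chance with 2 arrays against 2. An exact permutation test of a single gene could not go below a two-sided p of 0.333 in this design. The calls needed both sham arrays. Without sham array 1 or without sham array 2 no probe set passed in limma, with 5152 and 4816 at an unadjusted p under 0.05. These included 3488 and 3460 of the 3638 probe sets called with all arrays. Without castrated array 1 the counts were 901 higher and 1254 lower, and without castrated array 2 they were 316 and 499. With no filter on dim probe sets 68 passed as higher and 73 as lower.

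**Figure D1:**
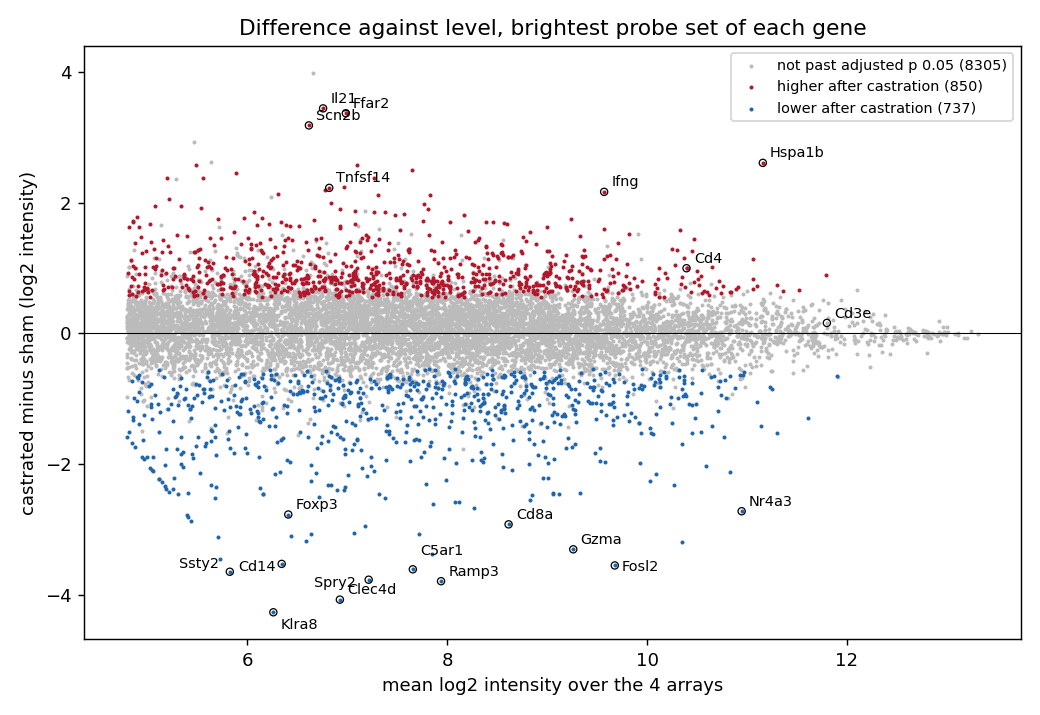
Castrated minus sham (log2 intensity, vertical axis) against the mean log2 intensity over the 4 arrays (horizontal axis), 1 point per gene for its brightest probe set. The 850 genes that rose are red, the 737 that fell are blue and the rest are grey, and circled genes are named, among them Il21 at 3.44 and Klra8 at -4.27.

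Among the genes of T helper 1 (Th1) cells and of signalling by interleukin 12, which drives that fate, 9 of the 23 tested genes rose and 2 fell. Ifng, the main Th1 cytokine, rose by 2.16 ± 0.19 log2, from a mean of 8.49 ± 0.20 (SD, n = 2) in sham to 10.65 ± 0.26 in castrated arrays (adjusted p = 0.00567). Tbx21, which encodes the Th1 transcription factor T-bet, rose by 1.17 ± 0.25 (adjusted p = 0.036). Lta and Tnf, 2 cytokines of the tumour necrosis factor family, rose by 1.90 and 1.86, and the chemokine receptor Cxcr6 rose by 1.83. Stat4, which carries the interleukin 12 signal, differed by -0.19 ± 0.16 (adjusted p = 0.444). The receptor subunit Il12rb1 differed by 0.97 ± 0.26 (adjusted p = 0.0596) and the phosphatase Ptpn1, which acts on JAK kinases, by 0.46 ± 0.15 (adjusted p = 0.0835), and neither passed. The castrated arrays lay apart for Il12rb1, at 6.14 and 6.91, against 5.55 on each sham array. Il12rb2 was too dim to be tested. As a set, the Th1 list did not pass (camera, adjusted p = 0.303). Adjusted over the list alone, 12 of its genes rose and 4 fell. Over all tested probe sets the 2 genes that fell were Fasl and Gzmb, which encode products of killer cells, by -0.98 and -3.06, and they were named after their values were seen. Gzmb differed by -2.43 without castrated array 1 and by -3.70 without castrated array 2. Over the same arrays the mean of the NK cell markers differed by -1.52 log2 and that of the CD8 T cell markers by -1.34.

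Gata3, the transcription factor of Th2 cells, rose by 1.02 ± 0.16 log2 (adjusted p = 0.0179), while 4 of the 11 tested Th2 genes fell, among them Ccr8 with a difference of -2.44 and Il4ra with -2.03. Of 12 Th17 genes 2 rose and 3 fell. Il6ra, a receptor for interleukin 6, rose by 0.98, although a dimmer probe set of it did not pass, and the nuclear receptor Rora fell by 0.98 and Ahr, the aryl hydrocarbon receptor, fell by 1.29. Il21 is the other Th17 gene that rose. In the follicular helper list 6 of 16 genes rose and none fell, including Il21, Cd40lg by 1.5 and Cd200 by 1.68. None of these lists passed as a set, with adjusted p = 0.48 for Th2, 0.609 for Th17 and 0.065 for follicular helper genes. Adjusted over the list alone, the higher and lower genes numbered 2 and 4 for Th2, 4 and 5 for Th17, and 7 and 1 for follicular helper genes. The follicular helper list passed without castrated array 1, at an adjusted p of 0.00102, and its mean was 7.69 and 7.93 on the sham arrays, 8.19 on castrated array 1 and 8.89 on castrated array 2. In camera with an estimated correlation the adjusted p of the follicular helper list was 0.86. The neutrophil markers were also highest on castrated array 2, and the means of the B cell, CD8 T cell and NK cell markers differed between the groups by -1.21, -1.34 and -1.52 log2.

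**Figure D2:**
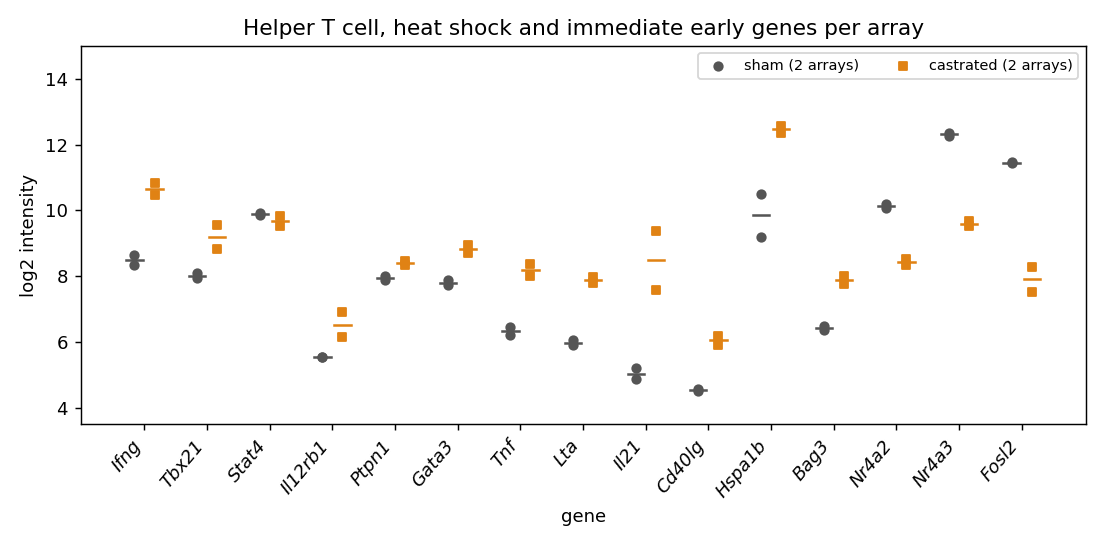
Log2 intensity (vertical axis) of 15 genes on each array, with circles for the sham arrays, squares for the castrated arrays and lines for the mean of 2 arrays. Ifng lies at 8.49 in sham and 10.65 in castrated arrays, whereas Stat4 differs by -0.19 and Nr4a3 by -2.72.

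Interferon-induced genes were higher in castrated arrays. Of the 30 tested genes of the type I interferon list 14 rose and none fell (camera, adjusted p = 0.00018, and adjusted p = 0.86 with an estimated correlation). The count adjusted over the list alone was 17 higher and 1 lower. Usp18, which restrains interferon signalling, rose by 1.86 log2, Ifit3 by 1.58 and Ifit1 by 1.39, and Parp14 rose by 0.92. A dimmer probe set of Parp14 did not pass. Of the 23 genes of the interferon-gamma list 7 rose, including the immunoproteasome subunits Psmb10 by 0.99 and Psmb8 by 0.87 and the GTPase Iigp1 by 1.64, and Irf8, a transcription factor of myeloid and B cells, fell by 0.94 (camera, adjusted p = 0.00576, and adjusted p = 0.86 with an estimated correlation). A dimmer probe set of Iigp1 did not pass. In the latter list 8 genes rose and 1 fell when adjusted over the list alone. The interferon-gamma list did not pass without castrated array 2 (adjusted p = 0.0694). On the same arrays the means of the B cell, CD8 T cell and NK cell marker lists differed by -1.21, -1.34 and -1.52 log2.

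Markers of cells that the sort should have removed were lower in castrated than in sham arrays. Cd8a, the co-receptor of CD8 T cells, fell by 2.92 ± 0.19 log2, from 10.07 ± 0.30 (SD, n = 2) to 7.15 ± 0.15 (adjusted p = 0.00351), and both of its other probe sets fell. Foxp3 fell by 2.77 ± 0.20, from 7.79 to 5.02 (adjusted p = 0.00379). Of the tested genes 4 of 6 in the CD8 T cell list, 10 of 19 in the B cell list, 6 of 10 in the NK cell list and 3 of 15 in the monocyte and macrophage list fell, and none rose. The camera adjusted p was 8.68e-05, 5.73e-08, 6.81e-05 and 0.00248 in that order, and the adjusted p was 0.86 for each list with an estimated correlation. The former values rest mainly on the spread between genes and say little about the spread between pools. The latter test can hardly call a list with so few arrays. Adjusted over the list alone, 6 CD8 T cell, 11 B cell, 6 NK cell and 5 monocyte and macrophage genes fell. With a filter at the 75th percentile, the NK cell and macrophage lists did not pass, at adjusted p = 0.0942 and 0.133. The B cell transcription factor Ebf1 fell by 1.95, the complement receptor Cr2 fell by 1.63 and the NK cell receptor Klra7 fell by 2.51. A dimmer probe set of Klra7 did not pass. Cd74 and H2-Aa, bright genes of B cells named after their values were seen, differed by -0.30 and -0.57 and did not pass. The other 4 NK cell genes, also named afterwards, were Prf1, Nkg7, Klrb1c and Tyrobp. Their brightest probe sets differed by 0.07, -0.16, -0.23 and -0.35 and did not pass. Among the 12 monocyte and macrophage genes that did not pass, Adgre1, Cd68, C1qc and Ctss differed by 0.39, 0.04, -0.02 and -0.08, and Cybb by -1.07.

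Cd4 rose by 1.0 ± 0.16 log2 (adjusted p = 0.0183) and by 1.84 on its other probe set, while Cd3e, a subunit of the T cell receptor complex that CD8 T cells share, differed by 0.16 ± 0.18 (adjusted p = 0.566). The complex was not level as a whole. The brightest probe sets of its subunits Cd3g and Cd247 rose by 0.73 and 0.72 (limma, adjusted p = 0.0281 and 0.0309), and that of Cd3d differed by 0.3 and did not pass. Of 26 genes of receptor signalling 9 rose and none fell, among them the adaptor Lcp2 by 1.29, Sit1 by 1.09 and Cd5 by 0.88 (camera, adjusted p = 0.0595). Of 18 genes of regulatory T cells 5 fell. Klrg1, which is also in the memory and effector list, fell by 2.26 and Tnfrsf9 fell by 1.65. Itgae, which is also in the CD8 T cell list, fell by 1.20, and Izumo1r rose by 1.16 (camera, adjusted p = 0.0581). Among the 12 genes of the list that did not pass, Ikzf2, Ikzf4 and Entpd1 differed by 0.09, 0.29 and 0.11, and Il2ra and Tnfrsf4 by -1.12 and -1.11. The counts adjusted over the list alone were 9 receptor signalling genes higher, and 2 regulatory T cell genes higher and 6 lower. The receptor signalling list passed under some alternatives, at an adjusted p of 0.0128 with the mean of all probe sets of a gene, 0.0222 with no filter, 0.0288 with an intensity trend, 0.0396 with log2 of the intensity plus 50, 0.0334 without sham array 1 and 0.0492 without castrated array 2. In camera with an estimated correlation the adjusted p was 0.86 for the receptor signalling list and for the regulatory T cell list. The mean of the regulatory T cell list was 7.99 and 8.13 on the sham arrays, 7.23 on castrated array 1 and 8.05 on castrated array 2. The lower mean thus lay mostly on castrated array 1.

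Neutrophil markers differed between the castrated arrays. The mean of 11 such genes was 7.50 and 7.13 on the sham arrays, 6.55 on castrated array 1 and 8.43 on castrated array 2. Among them Il1b fell by 1.25 log2, and S100a9 differed by -0.92 ± 0.65 (adjusted p = 0.359). The neutrophil list did not pass (camera, adjusted p = 0.906), passed as higher without castrated array 1 (adjusted p = 0.0104) and passed as lower without castrated array 2 (adjusted p = 0.0165). In camera with an estimated correlation the adjusted p of the neutrophil list was 0.979. Of 8 dendritic cell genes 3 fell, with a difference of -1.09 for Tcf4, although the median of the list was 0.41. Itgax and Clec4a2 of this list differed by 1.0 and 1.08 and did not pass. Of 8 erythroid genes Tfrc fell by 0.82. A dimmer probe set of Tfrc did not pass. Of 5 plasma cell genes Xbp1 fell by 0.84, although 1 of its dimmer probe sets did not pass. Of 3 genes of gamma-delta and invariant NK T cells Blk fell by 1.94, and it is also a B cell gene. Neither of the 2 tested platelet genes passed. The dendritic cell list had a camera adjusted p of 0.962, the erythroid list 0.286 and the plasma cell list 0.223. In camera with an estimated correlation the adjusted p of the plasma cell list was 0.86. Its mean was 8.52 and 8.88 on the sham arrays, 8.02 on castrated array 1 and 8.66 on castrated array 2. The plasma cell list passed as lower without castrated array 2, at an adjusted p of 0.0147, and the 2 smallest lists were not tested as sets.

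**Figure D3:**
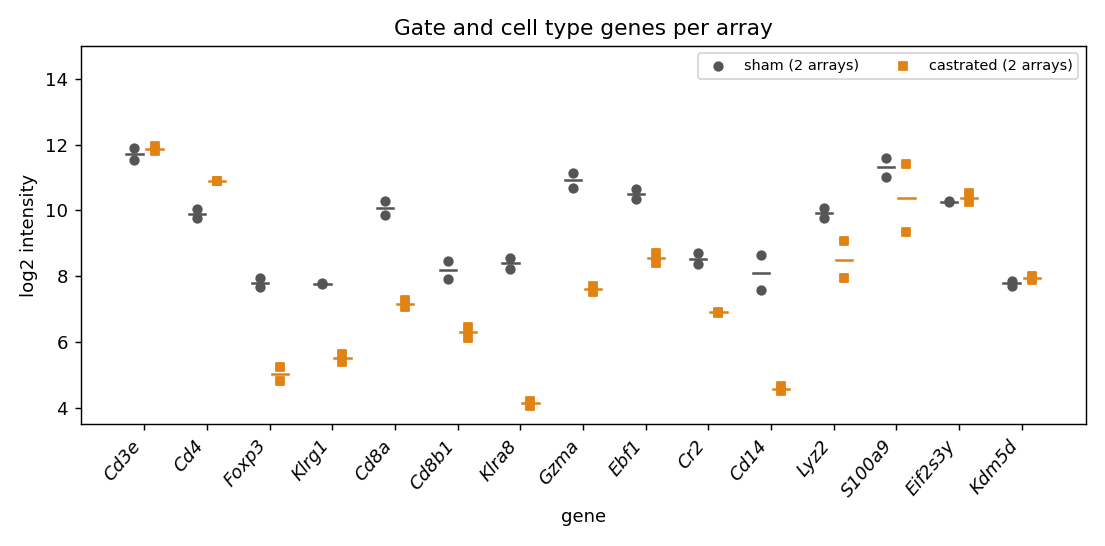
Log2 intensity (vertical axis) of 15 genes of the sorting gate, of other cell types and of the Y chromosome on each array, with circles for sham, squares for castrated and lines for the mean of 2 arrays. Castrated minus sham is -2.92 for Cd8a, -4.27 for Klra8, 1.0 for Cd4 and 0.16 for Cd3e.

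Of 20 tested genes of the androgen response list 5 fell and none rose (camera, adjusted p = 0.0581). Zbtb10 fell by 2.67 log2, Acsl3 fell by 2.46, Odc1, the first enzyme of polyamine synthesis, fell by 1.84 and Tsc22d3 fell by 1.4. Of the androgen genes 3 rose and 6 fell when adjusted over the list alone. The list passed without castrated array 1, at an adjusted p of 0.00981, with log2 of the intensity plus 50, at 0.0398, and with an intensity trend, at 0.0456. In camera with an estimated correlation the adjusted p of the androgen response list was 0.86. Both dimmer probe sets of Tsc22d3 differed in the same direction and did not pass. Of 14 glucocorticoid genes Tsc22d3, Klf9 and Cdkn1a fell, with differences of -1.4, -1.30 and -1.06, and Ddit4 rose by 1.14 (camera, adjusted p = 0.908). Dimmer probe sets of Klf9 and Cdkn1a did not pass. These genes moved on the same arrays as the lower B cell, CD8 T cell and NK cell markers.

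Among immediate early genes Nr4a3 fell by 2.72 ± 0.15 log2 (adjusted p = 0.00351), Fosl2 fell by 3.55, Nr4a2 fell by 1.70 and Rel fell by 1.89, whereas Fos, Jun and Ppp1r15a rose, by 0.89, 1.01 and 0.71. The last 3 were named after their values were seen, to complete the count. With 3 of 30 genes higher and 4 lower, the list did not pass (camera, adjusted p = 0.597). Of the 3 dimmer probe sets of Nr4a2, 1 did not pass. Among 20 targets of NF-kappaB 3 rose and 3 fell, with Ltb higher by 1.47 and Cd83, which B cells also express, at -1.53 (camera, adjusted p = 0.906).

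Heat shock genes were higher for a few members. Of 17 tested genes 4 rose and 1 fell (camera, adjusted p = 0.303). Hspa1b rose by 2.61 ± 0.41 log2 on its brightest probe set, and by 6.67 and 5.36 on the other 2. The brightest differed by 1.96 without sham array 1 and 3.26 without sham array 2. On the dimmest of these the sham arrays differed, at 4.2 and 6.55, and the castrated arrays lay at 12.07 and 12.02. The co-chaperone Bag3 rose by 1.46 ± 0.16 and Pdia4, of the endoplasmic reticulum, rose by 0.78. The cytosolic co-chaperone Dnaja1, named after its value was seen to complete the count, rose by 0.65, and Xbp1 fell by 0.84. The B cell markers differed by a mean of -1.21 log2 over the same arrays.

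Among survival genes 5 of 22 rose and 4 fell. The death receptor Fas rose by 1.04 log2 and Casp8 rose by 0.84, whereas the BH3 protein Bcl2l11 fell by 2.04 and the death receptor Tnfrsf10b was at least 5.06-fold lower, being at the floor on both castrated arrays (camera, adjusted p = 0.81). Of 29 memory and effector genes 7 rose and 2 fell, with S100a4 higher by 1.26 and Ctla2a at -1.10 (adjusted p = 0.437). Of 13 inhibitory receptors 4 rose, among them Vsir by 0.84 and Cd160 by 0.75 (adjusted p = 0.26). Without castrated array 1 the memory list and the inhibitory receptor list passed as higher, with adjusted p = 0.00793 and 0.00655. Over all 4 arrays the adjusted p with an estimated correlation was 0.95 and 0.86. On castrated array 2, which these passes rest on, the neutrophil markers had a mean of 8.43, against 6.55 to 7.50 on the other arrays, and the cell cycle genes 8.13, against 7.19 to 7.63. Among 25 inhibitors of cytokine signalling Dusp4 fell by 2.30 and Ptpn22 fell by 0.72, Pias2 fell by 0.76 and Pias3 rose by 0.93 (adjusted p = 0.561). Of the dimmer probe sets, 1 of Pias2 and 1 of Pias3 did not pass. Of 19 genes of naive cells Slfn2 rose by 0.82 and Ccr9 fell by 0.73 (adjusted p = 0.0581). Both dimmer probe sets of Ccr9 did not pass. In camera with an estimated correlation the adjusted p of the naive cell list was 0.86. Its mean was 9.95 and 9.92 on the sham arrays, 9.88 on castrated array 1 and 9.59 on castrated array 2. The list passed as lower without sham array 2, at 0.0361, without castrated array 1, at 0.00183, with no filter, at 0.00557, with an intensity trend, at 0.0222, and with log2 of the intensity plus 50, at 0.0344.

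None of 37 ribosomal protein genes passed, with a median difference of -0.02 log2 (camera, adjusted p = 0.422). Of 39 genes of oxidative phosphorylation Ndufb3 rose by 0.65 (adjusted p = 0.492). Of 18 tested genes of the glycolysis list Pfkm rose by 1.54 and Pfkl by 0.85, although neither dimmer probe set of Pfkl passed. The lactate transporter Slc16a3 fell by 2.12 (list in camera, adjusted p = 0.305). Gpi1 and Eno1 of this list were matched by synonym to Pigq and Eno1b, which differed by 0.21 and 0.43. The set tests of the list were therefore run with members other than those intended. The fry test called the glycolysis list as higher (adjusted p = 0.000937), whereas camera with an estimated correlation did not (adjusted p = 0.86). Of 16 cholesterol synthesis genes Cyp51, Mvk and Stard4 fell, with differences of -1.37, -0.88 and -0.73 (adjusted p = 0.437), and a dimmer probe set of Stard4 did not pass. Of 34 cell cycle genes Cenpa fell by 1.10, although its dimmer probe set did not pass, and the list did not pass (adjusted p = 0.85). It passed as higher without castrated array 1 (adjusted p = 6.14e-05) and as lower without castrated array 2 (adjusted p = 0.000735). Over all 4 arrays its adjusted p was 0.979 with an estimated correlation. The neutrophil list also passed in opposite directions in these fits, with means of 6.55 and 8.43 on castrated arrays 1 and 2.

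All mice were male, and the single-copy Y genes showed similar intensities in both groups. Eif2s3y differed by 0.12 ± 0.16 log2, Kdm5d by 0.16 ± 0.15 and Uty by -0.16 ± 0.16, and Xist, which is expressed from the inactive X chromosome of females, differed by -0.22 ± 0.24. None of these 4 passed, with adjusted p = 0.619, 0.474, 0.515 and 0.554. Ddx3y was not analysed here.

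**Figure D4:**
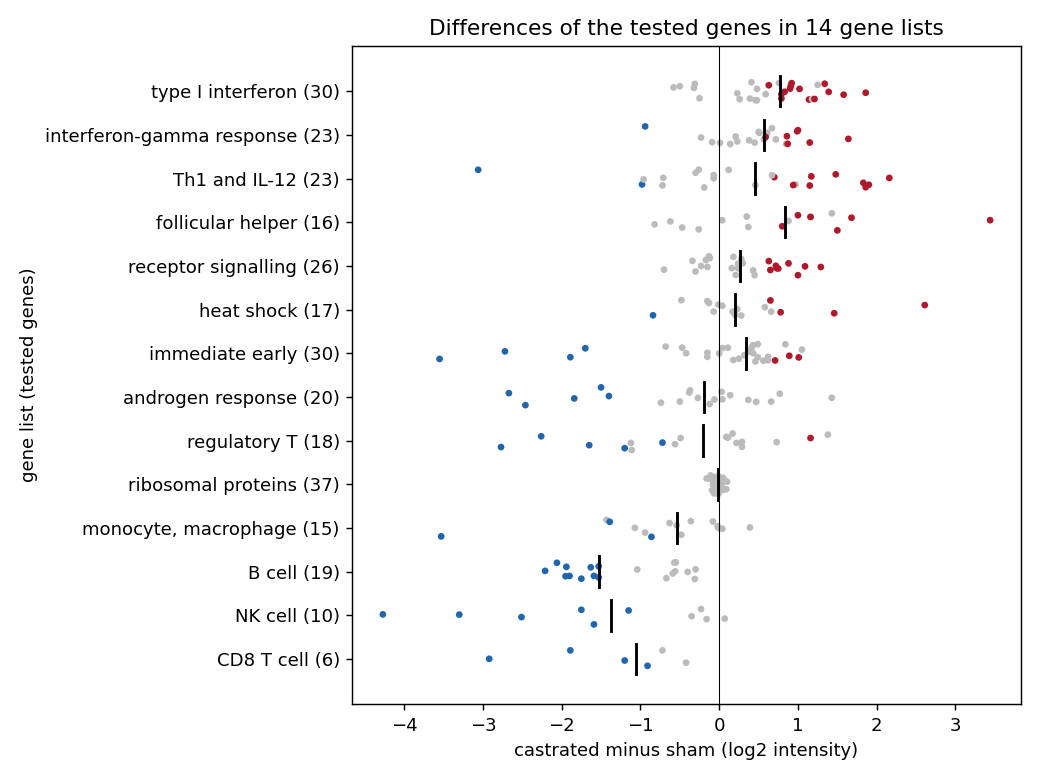
Castrated minus sham (log2 intensity, horizontal axis) of each tested gene in 14 gene lists (vertical axis, number of tested genes in parentheses), with genes that rose in red, genes that fell in blue, the others in grey and a black bar at the median. The median of the type I interferon list is 0.77 and that of the B cell list is -1.53.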

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

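The tests on the uniform share of other cells, on the CD4 T cell response, on RNA integrity, on receptor stimulation, on dilution and on the other splits of the arrays were chosen after the results were seen. The independent lists of B and NK cell genes and of chaperone genes were written before their values were seen. The tests of the uniform share, of receptor stimulation and of dilution were restated after their first outcomes were seen.

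The comparison leaves out the 22517 dim probe sets below the filter, and these were examined separately. When all probe sets were tested together in limma, 31 of the dim probe sets were higher in castrated arrays at an adjusted p under 0.05, a signal in probe sets that the filtered comparison leaves out. A further 33 were lower. At an unadjusted p under 0.05 the number of dim probe sets was 1299. In this test 14453 probe sets were at the floor on every array and the prior degrees of freedom were 0.35, against 3.68 in the filtered test.

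Markers of CD8 T cells, B cells, NK cells and of monocytes and macrophages were lower on the castrated arrays, although the sort for CD3, CD4 and the lack of GFP should have removed such cells. The neutrophil and dendritic cell lists did not pass (camera, adjusted p = 0.906 and 0.962). RNA of B and NK cells in the sham pools is a candidate explanation. A set of 24 further genes of these cells, none of them in the marker lists, had a median difference of -0.93 log2, with 11 lower and none higher. Most of the 24 were B cell genes, so this median says less about NK cells. Among the others Cma1 and Klrb1b fell by 2.05 and 1.75, but Klrb1f, Xcl1 and Fgl2 differed by -0.16, -0.21 and 0.29 and did not pass. Among bright genes of the B cell list, Cd74 differed by -0.30, from 12.96 to 12.65, and H2-Aa by -0.57, from 11.53 to 10.96. Cd83, also bright, fell by 1.53, from 12.07 to 10.54. The size of a share of B cell RNA stays open. A lower share of CD4 T cells with all other cell types raised alike was examined by comparing marker lists. The NK cell list lay apart from the dendritic cell list by -1.73 ± 0.30 (SE between arrays, with 0.58 between genes). Of the 28 pairs of 8 marker lists, 10 lay apart by more than 0.5 log2 and more than 2 of both SE. Permuting genes among the lists gave a permutation p of 9e-05, with genes not independent replicates. The lists thus did not move alike. This cannot decide against equal shares, because a gene's change also depends on its level in the CD4 T cells. Within the B cell list alone the differences ran from -0.30 for Cd74 to -2.21 for Fcrla. A response of the CD4 T cells themselves cannot be told apart from a difference in cell composition, which was not measured apart from the genes, such as the CD8 T cell list with its median of -1.05.

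Heat shock genes were higher on the castrated arrays for 4 members, with Hspa1b most. A heat shock response, in the animals or during handling, may be the source. A list of 17 further genes, mostly of chaperones, had a median difference of 0.08 ± 0.18 log2 (SE of the median). In it 1 gene was higher, Mrpl18, which encodes a mitochondrial ribosomal protein, and 1 was lower. A median of 0.1 or lower was set beforehand to count against this explanation. The median lay under that bound by less than its SE, a margin not in the bound as set, so the test is read as undecided. Among these genes a dimmer probe set of Dnajb4 rose by 1.63 (limma, adjusted p = 0.0233), while its brightest differed by 1.12 and did not pass. Poorer RNA integrity on one side is argued against: the 3' minus 5' signal of the actin and Gapdh control probe sets differed between groups by -0.09 ± 0.12 log2, within the bound of 0.5. Surgery itself and the handling of each group remain untested.

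Cytokine genes such as Ifng, Tnf, Lta and Il21 were higher on the castrated arrays. Stronger stimulation through the T cell receptor during sorting stays open, since 34 immediate early and stimulation-induced genes had a median difference of 0.21 ± 0.23 log2 (SE of the median), with 3 higher and 5 lower, and a later list of 14 of these genes, without the risers Fos and Jun, had a median of -0.54 ± 0.36. Dilution of CD4 T cell RNA on the sham arrays cannot be told apart from an effect of castration, because the answer turned on the Cd4 probe set used. The mean rise of the 9 called cytokine genes was 1.82 ± 0.26 (SE between genes, not between arrays). It lay -0.02 from that of the most raised Cd4 probe set but 0.83 above that of the brightest. Over all 15 cytokine genes of the list these gaps were -0.87 and -0.02. The 9 called genes were picked because they rose in these data, so their mean is high by selection and its gaps cannot decide. Of the 9 called genes, 5 rose by more than the most raised Cd4 probe set and 8 by more than the brightest. Of all 15 genes these numbers were 5 and 9. Il21, at 3.44, rose by more than either Cd4 probe set, which the means do not show.

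The 4 arrays can be split into 2 and 2 in 3 ways. The real split gave 3638 calls and the highest of the others 0, and 1 of the 3 splits, the real one, gave as many. At an unadjusted p under 0.05 in limma the other splits gave 159 and 63 probe sets. So few splits cannot give a share under 0.05.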

How the results depend on the processing

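No probe set passed in limma without either sham array, with 5152 and 4816 at an unadjusted p under 0.05, while calls were made without either castrated array. One alternative, leaving out the genes of the marker and heat shock lists, was chosen after seeing the data and gave 1732 higher and 1916 lower. Leaving out 1 array at a time, with the lone array of its group assumed to vary like the other group, gave 0 to 901 higher and 0 to 1254 lower probe sets, and 2 to 7 lists higher and 4 to 8 lower. Each fit had 1 residual degree of freedom fewer. With no filter the counts were 68 and 73, with 14453 probe sets at the floor on every array and 0.35 prior degrees of freedom. With a filter at the 75th percentile they were 1125 and 1155 of 11259 tested, and 1 list was lower. At an adjusted p under 0.1 they were 3257 and 3077. No list was called in either direction with an estimated correlation (0 higher, 0 lower), a test that can hardly call a list with so few arrays. The fry test called 1 higher and 1 lower. Quantile normalization, median centring, the other floor and constant and the variance models stayed within 1.5 times. The share of calls that were higher was 46.9%, and 38.8% to 51.4% over the alternatives that gave calls. The lowest correlation within a group exceeded the highest between groups by 0.033, by 0.014 with no filter and by 0.062 with the 75th percentile filter. The cause of these shifts was not tested. With the replicate block 1749 probe sets were higher and 2067 lower and 3 lists were higher and 4 lower, the added one being the follicular helper list (adjusted p = 0.0474). The replicate numbers share no stated origin, and same-numbered arrays deviated together with a correlation of 0.065. For 122 genes named here, 1249 of 1675 values under the alternatives kept their direction and side of the threshold, 417 kept the direction but no longer passed and 5 newly passed. Leaving out 1 array turned the direction of 4 genes that had not passed: Cd3e ranged from -0.023 to 0.34, Eif2s3y from -0.015 to 0.26, S100a9 from -1.95 to 0.11 and Xist from -0.51 to 0.07. Signal over background limits the 37.0% to 37.4% of probe sets at or under the floor.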

Other observations

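The tests of the clock and cyclic AMP lists were chosen after results were seen. Dimmer probe sets of some genes rose where the brightest did not, for genes singled out after their values were seen. Those of Hspa8, Ahsa1 and Dnajb1, which encode a constitutive chaperone and 2 co-chaperones, rose by 3.49, 3.05 and 2.02 log2, while the brightest probe sets of these genes differed by 0.28, 0.38 and 0.58 and did not pass. The same held for Evl, Anxa6, Ccdc88c and Kat2b, with rises of 3.19, 2.94, 2.65 and 2.09 on a dimmer probe set. Where in each transcript these probe sets lie was not analysed here. In all, 10 genes had a dimmer probe set that rose by at least 1.5 log2 and a brightest one that did not pass, and 10 genes had the same pattern for falls.

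Ssty2 and Orly, from multicopy families of the Y chromosome, were lower in castrated arrays, and Orly was looked up after Ssty2 was seen. Both tested probe sets of Orly fell, with differences of -3.09 and -2.37 log2, and Ssty2 was at the floor on both castrated arrays. Other probe sets of Orly and that of Ssty1 were below the filter, and no test of the family was run. The mean of Eif2s3y, Kdm5d and Uty was 7.77 on each sham array, 7.89 on castrated array 1 and 7.74 on castrated array 2.

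Among the 104 control probe sets 1 was lower in castrated arrays, a 3' probe set of the transferrin receptor, and none was higher.

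After Usp2, Nr4a3 and Fosl2 were seen among the falls, 2 further lists were written. Of 14 circadian clock genes Nr1d2 and Per2 fell, by 1.26 and 0.92 log2, and Ciart rose by 1.26, and the list did not pass (camera, adjusted p = 0.368). Of 16 genes linked to cyclic AMP signalling the phosphodiesterases Pde4b and Pde4d fell, by 0.99 and 1.82, and Nfil3 fell by 0.84, and this list did not pass either (adjusted p = 0.188). With an estimated correlation the adjusted p was 0.56 for each.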
